A study of Mus musculus with 11 samples.

How the data were processed

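The values in the deposited table are, per the submitters' processing notes and the numbers themselves, the natural log (ln) of 1 plus counts per 10000 in each cell. Counts within 0.001 of a whole number were recovered from them for 100% of non-zero values. The authors' cluster numbers and the deposited sort gate names of the wells are labels without a unit. Per the labels' protocols, single cells were sorted into plates, cDNA was pooled within a plate and 3' ends were sequenced on an Illumina NextSeq. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.5.3a, counted with featureCounts 1.5.3, handled with SAMtools 1.4.1 and clustered with Seurat, without a version. How the clusters were made beyond that is not given in the sources used here.

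The comparisons, the gene lists and the rule for named genes were chosen before the data were examined. So were, for the clusters, the settings with median-of-ratios size factors, without the block and without each set. All other settings given for the clusters, apart from cluster 3 in the model, were chosen after the data were seen. The plan put limma in place of the test on counts if the deposited table did not hold counts, and its unit is a log. The test on counts was not run on the recovered counts. The tracer comparisons were not run because no cell could be tied to a well. Splitting cluster 3, comparing clusters 1 and 2 directly, the plate-level tracer comparison, the split of cluster 4 by Sst and every test in the closing part were chosen after the data were seen. The plan set each class against the mean of the others. Cluster 3 was left out of that model after it was seen to mix 2 depth populations. The comparison of the whole of cluster 3 had been run and looked at before it was set aside: 4313 of 10960 genes passed, 736 higher and 3577 lower. Of these 4313, 1125 changed sign with median-of-ratios size factors on summed counts, and 1272 with summed counts scaled to the total. The named genes of that comparison are therefore not given.

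The main test used limma 3.58.1 in R 4.3.3, with trend and robust options, on the mean over cells of log2(1 + counts per 10000) for each set and cluster. The set was a block, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genes needed a mean of at least 0.05 counts per 10000. Log2 differences on this scale understate the change of genes with low levels, and low levels also depend on depth. Deviations from the mean of each cluster over the sets were correlated between clusters. The same set gave 0.555 to 0.866, so the set was kept as a block. Other sets gave -0.720 to 0.00171, and values below 0 follow there because the deviations sum to 0 over the sets. Plates within a set were treated as technical. Low levels, such as Vip at 0.215 in cluster 1, are not read as expression because cDNA was pooled within a plate.

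Lists were tested with camera from limma, which compares a list with all other genes, at a fixed correlation between genes of 0.01 and again with the correlation estimated for each list. Of 46 lists called in the comparisons of clusters 1, 2 and 4, 34 lost the call with the estimated correlation. The test fry was also run: its main p asks whether genes of a list move on balance in 1 direction, its mixed p whether they change in either direction, and neither compares with other genes. Fibroblast, mural, macrophage, lymphocyte, erythrocyte, brown adipocyte and skeletal muscle markers had too few tested genes for camera.

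Genes are named if they were fixed in advance, are among the 4 members of a list with the smallest p, or are among the 6 genes with the smallest p in each direction. The fixed genes were Th, Dbh, Slc18a2, Slc6a2, Npy, Chat, Slc18a3, Slc5a7, Vip, Sst, Ret, Gfra2, Gal, Penk, Ntrk3, Prph, Nefm, Atf3 and Adra2a, of which Penk was not analysed here, and 1 more gene that is not reported here. The part of the rule for tracer comparisons had nothing to apply to. Gene positions come from GENCODE M21 by symbol, which matched 18737 of 19444 symbols. Intervals for shares are 95% Clopper-Pearson intervals and cover counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation, permutations and figures. No doublet caller was run.

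To see what the test finds, cells of cluster 1 were split at random within each set and counts were lowered by known factors. With groups of equal size it called 66 of 94 genes changed 2-fold, 82 of 83 changed 4-fold and 5 of 10211 unchanged genes. With groups of the size of cluster 4 it called 41 of 93 changed 2-fold, 71 of 87 changed 4-fold and 4 of 10178 unchanged genes. Both groups were cluster 1 cells of like depth, so these rates need not hold between clusters that differ in depth. Alternatives were median-of-ratios size factors with limma, summed counts with voom weights, thinning to 15000 counts per cell, no block, leaving out each set, a filter of 0.5, weights by cell number, a smaller pseudocount, cluster 3 in the model, and leaving out the neurons with the fewest counts or the most glial counts. Median-of-ratios size factors and voom weights were applied to counts summed per set and cluster, and summed counts scaled to the total were also tried. Log2 differences from these settings, and from the smaller pseudocount, are on other scales than the main ones. Thinning kept 791 cells and left out 87. Cluster 3 in the model also added cluster 3 to the mean that clusters 1, 2 and 4 were each set against.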

Results

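RNA was sequenced from single cells of the stellate ganglion of 6 male C57BL/6J mice. The stellate ganglion is the sympathetic ganglion at the base of the neck. Each mouse received the retrograde tracer CTB-488 in the forelimb and CTB-555 in the interscapular brown adipose tissue (iBAT), 3 days before the ganglia were taken. Ganglia of 2 mice were pooled in each of 3 sets, so the set is the replicate and n = 3. Cells were sorted into 11 plates, with 4 plates in Set 1, 4 in Set 2 and 3 in Set 3. The sort record lists 1039 wells, and the expression table holds 19444 genes in 333 cells of Set 1, 326 of Set 2 and 219 of Set 3. The table held 30518080 counts in total, with 2050165 to 3373157 counts per plate. The median cell had 32923.5 counts and 6397.5 detected genes. The authors' annotation places each cell in 1 of 4 numbered clusters and gives them no cell type names. Cluster 1 held 388 cells, cluster 2 held 335, cluster 3 held 101 and cluster 4 held 54. Where clusters are compared below, the p-values describe how well a difference repeats over sets, because the clusters are groups of cells in this same dataset.

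The series asks about neurons traced from iBAT and from the forelimb. The sort record names a gate for each well, and A555 is read here as CTB-555 and A488 as CTB-488. A555 was recorded for 433 wells, which is 41.7% (95% Clopper-Pearson interval 38.7 to 44.7). A488 was recorded for 220 wells, or 21.2% (18.7 to 23.8), and A000, read here as neither tracer, for 374 wells, or 36.0% (33.1 to 39.0). The other 12 wells were recorded as misses. The A555 share was 41.3% ± 3.85 (SD, n = 3 sets), the A488 share 21.7% ± 4.82 and the A000 share 35.8% ± 1.32. The A488 share was lowest in Set 1, at 16.9%, and highest in Set 3, at 26.6%. Every plate but plate 11 had 34 to 36 A000 wells, and plate 11 had 22. The shares of traced and A000 wells may therefore reflect how plates were filled. They and their intervals are not read as shares of the ganglion. The sources used here do not tie a cell of the expression table to a well, so no cell has a tracer label and traced populations were not compared gene by gene.

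Plates differed in tracer mix, which allowed a weaker comparison that was added after the data were seen. A555 made up 51.8% to 78.3% of the traced wells of a plate. Over the 11 plates this share had a Pearson r of 0.197 with the share of cluster 1 cells, 0.216 with cluster 2, -0.238 with cluster 3 and -0.451 with cluster 4. Two-sided permutation p-values were 0.548, 0.526, 0.483 and 0.164, each 0.548 after adjustment over the 4 relations. Spearman's rho was 0.0182, 0.127, -0.245 and -0.573, with permutation p-values of 0.968, 0.714, 0.469 and 0.0705 and adjusted values of 0.968, 0.951, 0.938 and 0.282. Within sets, r was -0.188, 0.180, -0.0547 and 0.0453, with exact permutation p-values of 0.618, 0.637, 0.880 and 0.905 and an adjusted value of 0.905 for each. Without the 2 plates farthest from the median, r was 0.402, -0.0431, -0.271 and -0.359. With 1 set left out, cluster 3 had an r of 0.773 without Set 1 (unadjusted p 0.0315) and -0.753 without Set 3 (unadjusted p 0.0300), and cluster 4 had -0.753 without Set 2 (unadjusted p 0.0459). These permutations moved plates between sets, so their p-values also take in differences between the pools. Inside Sets 1, 2 and 3 alone, r was -0.751, 0.217 and 0.771 for cluster 3 and 0.697, 0.231 and -0.859 for cluster 4. Across genes, limma with the set as a block called 0 of 10464 genes at an adjusted p under 0.05, with 528 at an unadjusted p under 0.05 where 523.2 would be expected by chance. The smallest adjusted p was 0.228. Without the set in the model limma again called 0 genes, with 1518 at an unadjusted p under 0.05 and a smallest adjusted p of 0.182. A plate holds cells of every gate, so these values set no bound on differences between traced neurons.

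**Figure D1:**
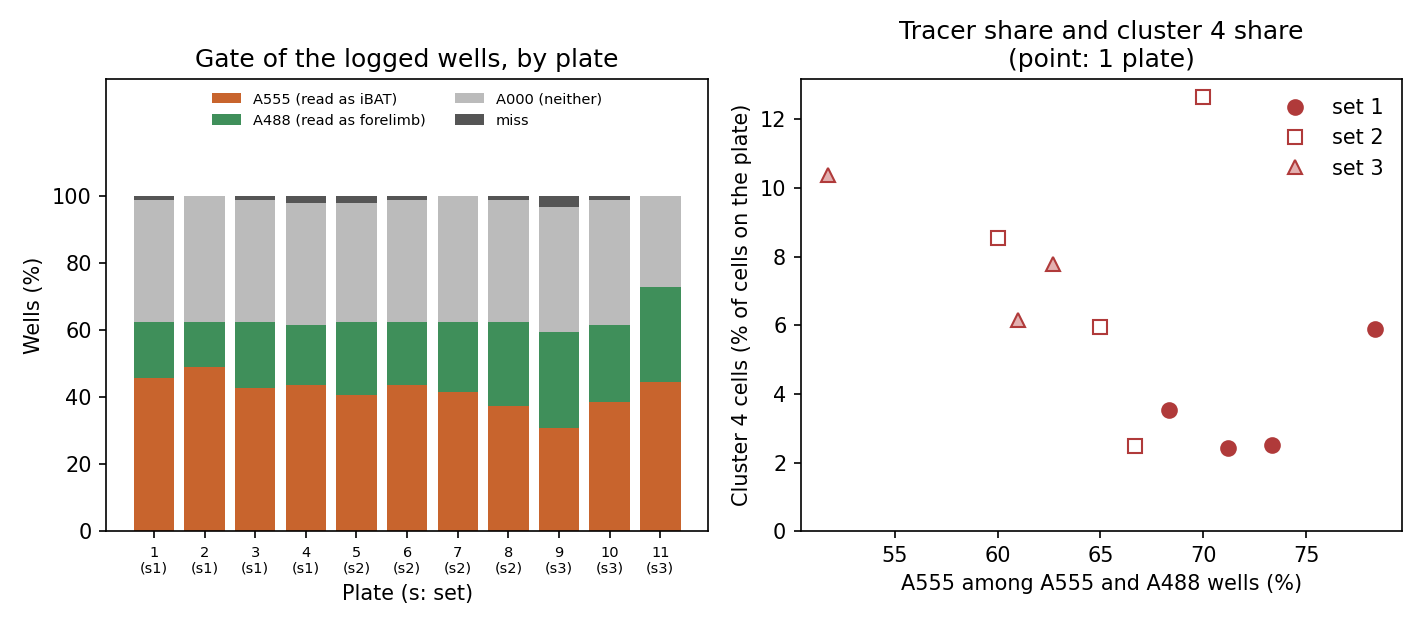
Left, gates of the logged wells of each of the 11 plates in percent. Right, each point is a plate, with the A555 share of traced wells in percent on the horizontal axis, the share of cells in cluster 4 in percent on the vertical axis, and sets told apart by marker. Pearson's r was -0.451 over all plates and 0.0453 within sets.

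Cluster 4, with 6.15% of the cells (95% Clopper-Pearson interval 4.65 to 7.95), carried the cholinergic and Vip transcripts. Vip, which encodes vasoactive intestinal peptide, averaged 54.1 ± 4.14 counts per 10000 (SD, n = 3 sets) in cluster 4, 0.215 ± 0.120 in cluster 1 and 0.232 ± 0.0887 in cluster 2. Slc18a3, the vesicular acetylcholine transporter, averaged 5.11 ± 0.956 against 0.0159 and 0.0488, and Slc5a7, the high-affinity choline transporter, 2.21 ± 0.590 against 0.00887 and 0.00760. Chat, which makes acetylcholine, was also higher but sparse, at 0.507 ± 0.0770 in cluster 4. Transcripts for noradrenaline handling were lower in the same cells. Slc6a2, the noradrenaline transporter, averaged 1.67 ± 0.856 against 16.4 ± 3.67 in cluster 1 and 21.6 ± 5.61 in cluster 2, and Dbh, which makes noradrenaline, 6.84 ± 0.670 against 22.0 ± 0.963 and 27.7 ± 2.71. Th, which catalyses the rate-limiting step of catecholamine synthesis, was lower but remained abundant, at 24.6 ± 8.99 against 49.0 ± 11.8 and 63.0 ± 15.7.

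Against the mean of clusters 1 and 2, limma gave a log2 difference of 5.22 (SE 0.0584, adjusted p 3.56e-17) for Vip and 2.44 (SE 0.0644, adjusted p 1.31e-12) for Slc18a3. Slc6a2 was lower by a log2 difference of -2.94 (SE 0.0493, adjusted p 5.93e-15), Dbh by -1.83, Slc18a2, the vesicular monoamine transporter, by -1.97, and Th by -1.70. The other genes with the smallest p-values among those higher were Cartpt at 2.59, Ass1, an enzyme of arginine synthesis, at 2.08, Ppp1r1c at 1.22 and Spats2l at 1.06. Among those lower they were Cplx2, a complexin of the synaptic release machinery, at -2.32, the copper transporter Slc31a1 at -2.33 and the monoamine oxidase Maob at -1.78. All of these moved the same way in 3 of 3 sets. Of the other genes named in advance, Slc5a7 (1.43), Gfra2 (0.96), Sst (0.90), Ret (0.87), Nefm (0.58), Chat (0.51) and Prph (0.44) were higher. Npy (-3.55, adjusted p 0.00332), Gal (-2.77, adjusted p 0.00157) and Ntrk3 (-0.13) were lower. Adra2a (0.02, adjusted p 0.856) and Atf3 (0.16, adjusted p 0.161) did not pass. Without Set 1 the adjusted p of Npy was 0.0779 and that of Atf3 0.0146. Atf3 also passed after thinning (0.16, adjusted p 0.0114) and without the 2 cells with the most Atf3 (0.06, adjusted p 0.0291). On summed counts it passed with median-of-ratios size factors (adjusted p 0.0212) and with voom weights (adjusted p 0.0176). Its difference of 2.57 with size factors is on the scale of summed counts, where scaling only to the total also gave 2.57. Npy lost its call with voom weights (adjusted p 0.0851), and Prph without the set in the model (adjusted p 0.217).

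By list, 8 of 10 tested cholinergic genes were higher in cluster 4 and 2 lower, also when adjusted over the list alone (adjusted p 1.77e-10; adjusted p = 0.0227 with an estimated correlation). All 8 markers of cholinergic sympathetic neurons were higher, and 8 when adjusted over the list alone (8.37e-17; 0.0158 with an estimated correlation). Of 15 noradrenergic genes 12 were lower and 0 higher, and 12 and 0 when adjusted over the list alone (4.57e-18; 0.0158 with an estimated correlation); Gch1, which makes a cofactor of Th, had a log2 difference of -1.47. Neuropeptides went both ways, with 7 of 12 higher and 2 lower, or 9 and 2 when adjusted over the list alone (2.28e-06; 0.0399 with an estimated correlation). Cartpt averaged 18.5 ± 8.44 and Calcb 1.61 ± 0.385 in cluster 4, against 0.118 and 0.00155 in cluster 2. Of 68 nuclear OXPHOS subunits, the parts of the respiratory chain and ATP synthase, 51 were higher and 1 lower, or 52 and 1 when adjusted over the list alone (4.04e-18). Their median log2 difference was 0.21, and the adjusted p = 0.0654 with an estimated correlation. Cox6b1, for example, averaged 28.2 ± 2.49 in cluster 4 against 19.5 ± 2.26 and 23.0 ± 2.06.

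Of 18 immediate early genes 12 were higher in cluster 4, or 14 when adjusted over the list alone, and 0 lower (3.36e-09; adjusted p = 0.0666 with an estimated correlation). Fos averaged 0.923 ± 0.263 there, against 0.436 ± 0.187 and 0.351 ± 0.138. Immediate early genes also respond to tissue dissociation. Of 8 mitochondrially encoded genes 5 were higher and 2 lower, or 6 and 2 when adjusted over the list alone (0.00819; adjusted p = 0.161 with an estimated correlation). The axon injury list had 9 of 14 higher and 3 lower, the same counts when adjusted over the list alone (0.00376; adjusted p = 0.40 with an estimated correlation), and its mean, unlike its median and its test, was below 0. Receptors for transmitters and peptides had 6 of 20 higher and 12 lower, the same counts when adjusted over the list alone (0.0278; adjusted p = 0.254 with an estimated correlation). The angiotensin receptor gene Agtr1a averaged 0.0285 ± 0.0128 in cluster 4 against 0.885 ± 0.146 and 1.16 ± 0.0959. Cholesterol biosynthesis genes had 7 of 23 higher and 0 lower, the same when adjusted over the list alone (0.0368; adjusted p = 0.173 with an estimated correlation). Cytosolic ribosomal protein genes had 11 of 79 higher and 1 lower, or 8 and 1 when adjusted over the list alone (0.0235; adjusted p = 0.518 with an estimated correlation). The general sympathetic markers had 7 of 12 lower and 2 higher, also when adjusted over the list alone (1.24e-05; 0.0492 with an estimated correlation).

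Glial and Schwann cell markers had 2 of 8 higher and 1 lower in cluster 4, or 4 and 1 when adjusted over the list alone (0.00508; adjusted p = 0.391 with an estimated correlation). S100b averaged 0.786 ± 0.126 there, against 0.0741 ± 0.0120 and 0.185 ± 0.145, and Pmp22 10.7 ± 1.51 against 6.19 ± 0.771 and 7.28 ± 1.18. Without the 10% of neurons with the most glial marker counts the median of the list went from 0.37 to -0.06. No call was made in cluster 4 for dense-core granule proteins, growth factor and cytokine receptors, potassium channels, sodium, calcium and HCN channels, axon guidance, adhesion genes, the neuronal cytoskeleton, heat shock, the interferon response, Hox genes, endothelial, sensory neuron or chromaffin markers, whose adjusted p-values ran from 0.0655 for chromaffin markers to 0.914 for the receptors. In total 2608 of 10564 genes passed, 1305 higher and 1303 lower. The sets pooled ganglia, and without the set in the model 1118 genes passed.

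Cluster 1 was the Npy and Gal cluster. Npy, which encodes neuropeptide Y, a co-transmitter of noradrenaline, averaged 183 ± 14.7 counts per 10000 (SD, n = 3 sets) in cluster 1, 25.7 ± 10.3 in cluster 2 and 3.48 ± 1.10 in cluster 4. Gal, which encodes galanin, averaged 53.8 ± 8.57, 10.1 ± 2.96 and 2.08 ± 0.772. Fst, which encodes the activin-binding protein follistatin, averaged 2.58 ± 0.264 in cluster 1, 0.0579 ± 0.0258 in cluster 2 and 0.0180 ± 0.0193 in cluster 4. Epha5, an ephrin receptor, averaged 7.36 ± 1.13, 2.24 ± 0.352 and 1.87 ± 0.759, and Ncald, a neuronal calcium sensor, 10.8 ± 0.617, 4.22 ± 0.442 and 2.26 ± 0.211.

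Against the mean of clusters 2 and 4, limma gave a log2 difference of 4.61 (SE 0.348, adjusted p 0.00205) for Npy, 3.20 (SE 0.235, adjusted p 0.00140) for Gal and 1.62 (SE 0.0431, adjusted p 4.69e-12) for Fst. Without Set 1 the adjusted p was 0.0780 for Npy and 0.0559 for Gal. The other smallest p-values among genes higher belonged to the long non-coding RNA gene B230312C02Rik (2.17), Ncald (1.73), Epha5 (1.48), Maob (1.46) and Nt5dc2 (1.14). Among genes lower they belonged to Vip (-2.60), Ddah1 (-1.24), Slc18a3 (-1.24), Ass1 (-1.17), Gfra2 (-1.11) and Dmkn (-0.98), and all 3 sets showed each direction. Gfra2, a receptor subunit for neurturin, averaged 0.0601 ± 0.0159 in cluster 1, 0.992 ± 0.135 in cluster 2 and 1.90 ± 0.112 in cluster 4. Slc6a2 (1.19), Slc18a2 (0.97), Dbh (0.67) and Th (0.58) were higher against this mean, although mean levels of Slc6a2, Dbh and Th were higher in cluster 2 than in cluster 1. Slc5a7 (-0.71), Ret (-0.63), Adra2a (-0.44), Sst (-0.39) and Chat (-0.26) were lower. The call for Th was lost without the set in the model (0.58, adjusted p 0.187) and without the neurons richest in glial counts (0.46, adjusted p 0.206). It was also lost with voom weights (0.29, adjusted p 0.0537). Nefm (0.18, adjusted p 0.0233), Ntrk3 (0.09, adjusted p 0.0235) and Prph (-0.20, adjusted p 0.00487) passed by little, and each lost its call without Set 1, with adjusted p-values of 0.0956, 0.102 and 0.0832. Without Set 2 the values of Nefm and Ntrk3 were 0.184 and 0.326, and without Set 3 those of Nefm and Prph were 0.0798 and 0.0625. Atf3 did not pass (adjusted p 0.583).

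Of 68 nuclear OXPHOS subunits 48 were lower in cluster 1 and 1 higher, or 56 and 1 when adjusted over the list alone (adjusted p 1.34e-22; adjusted p = 0.0532 with an estimated correlation). With cluster 3 in the model their median log2 difference was -0.03 in place of -0.19, and 0 were lower and 2 higher. That model sets cluster 1 against a mean that includes cluster 3, so it measures another difference. Cox6c averaged 10.8 ± 1.10 in cluster 1, 15.7 ± 1.54 in cluster 2 and 15.3 ± 1.47 in cluster 4. Hox genes, which mark position along the body axis, had 3 of 6 higher and 0 lower, also when adjusted over the list alone (0.000195; adjusted p = 0.0532 with an estimated correlation). Hoxc9 averaged 0.433 ± 0.0682 against 0.0223 ± 0.0213 and 0.166 ± 0.0305. Noradrenergic genes had 11 of 15 higher and 0 lower, also when adjusted over the list alone (1.85e-15; 0.0219 with an estimated correlation). Cholinergic genes had 8 of 10 lower and 1 higher, also when adjusted over the list alone (5.88e-10; 0.0251 with an estimated correlation), and all 8 cholinergic neuron markers were lower, 8 when adjusted over the list alone (1.07e-15; 0.0219 with an estimated correlation). The differences of clusters 1, 2 and 4, each against the mean of the others, sum to 0 for every gene. Calls for 1 cluster therefore partly restate calls for another, here those for cluster 4. Neuropeptides had 7 of 12 lower and 2 higher, the same when adjusted over the list alone (0.000171; adjusted p = 0.0532 with an estimated correlation). Their median was -0.25 and their mean 0.13, because the 2 that were higher, Npy and Gal, moved furthest. The sympathetic markers had 6 of 12 higher and 2 lower (0.000167; adjusted p = 0.0532 with an estimated correlation), and chromaffin markers 3 of 4 higher and 1 lower (0.00347; adjusted p = 0.0953 with an estimated correlation), both counts the same when adjusted over the list alone.

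Immediate early genes had 5 of 18 lower in cluster 1, or 6 when adjusted over the list alone, and 0 higher (0.00450; adjusted p = 0.315 with an estimated correlation). Ribosomal protein genes had 8 of 79 higher and 0 lower, also when adjusted over the list alone (0.00426; adjusted p = 0.537 with an estimated correlation). The neuronal cytoskeleton had 10 of 21 higher and 5 lower, or 10 and 7 when adjusted over the list alone (0.0416; adjusted p = 0.210 with an estimated correlation). Stmn2 averaged 30.2 ± 3.16 in cluster 1 and 23.4 ± 3.79 in cluster 4, while the neurofilament gene Nefl averaged 3.60 ± 0.948 and 9.35 ± 2.10. The remaining lists had no call, with adjusted p-values from 0.0640 for axon injury to 0.888 for growth factor receptors. Among their members, the adhesion gene Cadm1 averaged 8.15 ± 0.861 in cluster 1 against 4.65 ± 0.902 and 1.72 ± 0.0803, and the potassium channel subunit gene Kcnmb4 1.48 ± 0.211 against 0.363 ± 0.0480 and 0.120 ± 0.0562. In total 1500 of 10564 genes passed, 612 higher and 888 lower. Without the set in the model 586 genes passed, and between 877 and 998 passed with 1 set left out.

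**Figure D2:**
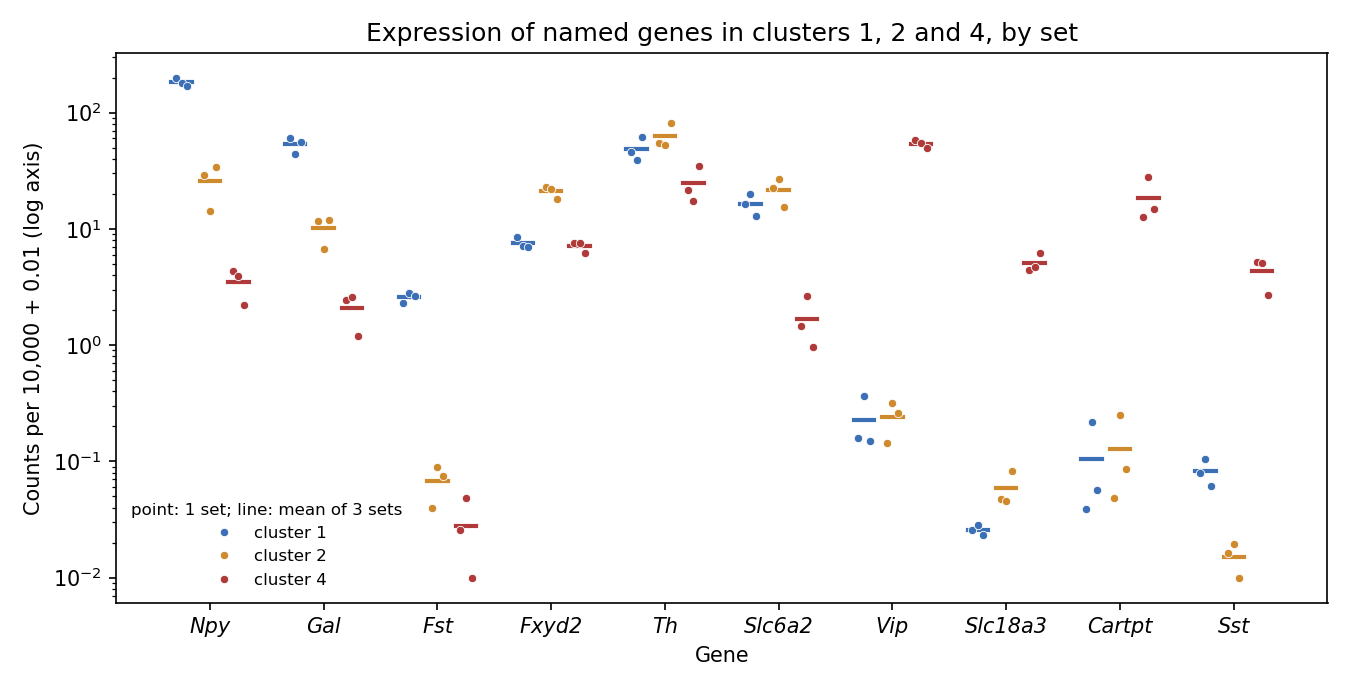
Levels of named genes in clusters 1, 2 and 4, as counts per 10000 plus 0.01 on a log axis. Points are the 3 sets and lines their means. Vip was at 54.1 in cluster 4 and at 0.215 in cluster 1, while Npy was at 183 in cluster 1 and 3.48 in cluster 4.

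Among clusters 1, 2 and 4, cluster 2 had the highest mean levels of Slc6a2, Th and Dbh, and its Npy and Gal levels lay between those of clusters 1 and 4. Fxyd2, a regulatory subunit of the sodium pump, averaged 21.1 ± 2.52 counts per 10000 (SD, n = 3 sets) in cluster 2 against 7.50 ± 0.888 in cluster 1 and 7.10 ± 0.756 in cluster 4. Atp6v1b2, a subunit of the proton pump that acidifies vesicles, averaged 17.7 ± 4.97 against 8.26 ± 2.15 and 7.91 ± 2.19. Cpne8 was lower at 0.0728 ± 0.0146 against 1.64 ± 0.165 and 4.19 ± 0.764, and Elmo1, which acts in Rac signalling, at 0.0219 ± 0.00977 against 0.787 ± 0.0619 and 1.97 ± 0.302.

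Against the mean of clusters 1 and 4, limma gave log2 differences of 1.75 (SE 0.0493, adjusted p 9.89e-12) for Slc6a2, 1.49 (SE 0.0499, adjusted p 7.67e-11) for Fxyd2, 1.27 for Cplx2, 1.26 for Slc31a1, 1.15 for Dbh and 1.05 for Atp6v1b2. Lower genes were Vip (-2.62), Cpne8 (-1.62), Slc18a3 (-1.20), Pdlim7 (-1.18), Elmo1 (-1.01) and Lxn (-0.87), and all 3 sets showed each direction. Th (1.12), Slc18a2 (1.01) and Adra2a (0.42), an inhibitory adrenergic receptor, were higher as well. Nefm (-0.75), Slc5a7 (-0.71), Sst (-0.50), Chat (-0.26), Ret (-0.25, adjusted p 0.00582) and Prph (-0.24) were lower. The call for Ret was lost without Set 1, at an adjusted p of 0.0907, and without Set 3, at 0.116, and those for Ret and Prph without the set in the model, at 0.630 and 0.805. Npy (-1.06, adjusted p 0.171), Gal (-0.43, adjusted p 0.399), Gfra2 (0.15, adjusted p 0.0624), Ntrk3 (0.04, adjusted p 0.349) and Atf3 (-0.08, adjusted p 0.582) did not pass. Npy passed without Set 2, at an adjusted p of 0.0272, and Gal without Set 3, at 0.0210. Gfra2 passed on summed counts with median-of-ratios size factors (1.54, adjusted p 4.52e-06) and voom weights (1.66), and with the smaller pseudocount (0.94, adjusted p 1.88e-05). These differences are on other scales than the 0.15 of the main fit.

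Of 15 noradrenergic genes 11 were higher in cluster 2 and 0 lower, also when adjusted over the list alone (adjusted p 7.36e-16; 0.0183 with an estimated correlation). Cholinergic genes had 8 of 10 lower and 1 higher, or 8 and 2 when adjusted over the list alone (4.20e-10; 0.0183 with an estimated correlation), and cholinergic neuron markers 7 of 8 lower and 0 higher, or 7 and 1 (4.45e-12; 0.0183 with an estimated correlation). As for cluster 1, these calls are not independent of those for cluster 4. Neuropeptides had 6 of 12 lower and 0 higher, also when adjusted over the list alone (4.20e-10; 0.0183 with an estimated correlation). Transmitter and peptide receptors had 9 of 20 higher and 4 lower, or 11 and 4 when adjusted over the list alone (0.00715; adjusted p = 0.174 with an estimated correlation). The kappa opioid receptor gene Oprk1 averaged 0.246 ± 0.0538 in cluster 2 against 0.00501 and 0.00932, and Adra2a 0.891 ± 0.234 against 0.235 ± 0.0336 and 0.563 ± 0.109. Adhesion genes had 10 of 26 lower and 5 higher, also when adjusted over the list alone (0.00259; adjusted p = 0.163 with an estimated correlation), and Pcdh7 averaged 0.0498 ± 0.0297 against 1.29 ± 0.280 and 0.456 ± 0.0764. The sympathetic markers had 6 of 12 higher and 2 lower, also when adjusted over the list alone (9.70e-05; adjusted p = 0.0712 with an estimated correlation).

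Immediate early genes had 8 of 18 lower in cluster 2, or 10 when adjusted over the list alone, and 0 higher (7.35e-09; adjusted p = 0.0804 with an estimated correlation). Ribosomal protein genes had 23 of 79 lower and 1 higher, or 31 and 1 when adjusted over the list alone (7.14e-09; adjusted p = 0.174 with an estimated correlation); Rps14 averaged 8.33 ± 0.615 against 10.0 ± 0.756 and 10.4 ± 1.03. Cholesterol biosynthesis had 6 of 23 lower and 1 higher, the same when adjusted over the list alone (0.00227; adjusted p = 0.0804 with an estimated correlation). Mitochondrially encoded genes had 3 of 8 lower, or 6 when adjusted over the list alone (0.000517; adjusted p = 0.0804 with an estimated correlation). The medians of both lists turned above 0 with cluster 3 in the model, and so in the mean set against cluster 2. Axon injury genes had 5 of 14 lower and 1 higher, or 8 and 1 when adjusted over the list alone (8.80e-05; adjusted p = 0.260 with an estimated correlation). Interferon response genes had 6 of 22 lower and 1 higher, the same when adjusted over the list alone (0.0197; adjusted p = 0.567 with an estimated correlation), with a median above 0 on summed counts with voom weights and with the smaller pseudocount. Hox genes had 2 of 6 lower and 1 higher, the same when adjusted over the list alone (0.0385; adjusted p = 0.174 with an estimated correlation). Glial markers had 4 of 8 lower and 0 higher, also when adjusted over the list alone (0.000203; adjusted p = 0.248 with an estimated correlation). The remaining lists had no call, with adjusted p-values from 0.199 for the cytoskeleton to 0.835 for heat shock. In total 1301 of 10564 genes passed, 733 higher and 568 lower. Without the set in the model 458 genes passed, and between 664 and 814 passed with 1 set left out.

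Clusters 1 and 2, which hold most of the noradrenergic cells, were also compared directly, a comparison added after the data were seen. Npy was higher in cluster 1 by a log2 difference of 3.78 (SE 0.401), Gal by 2.41 (SE 0.271), B230312C02Rik by 1.92, Fst by 1.60 (adjusted p 8.09e-11), Epha5 by 1.42, Bub3 by 1.29, Sctr, the secretin receptor gene, by 1.23, Nt5dc2 by 1.03 and Nefm by 0.62. Without Set 1 the adjusted p was 0.190 for Npy and 0.173 for Gal. Fxyd2 was lower in cluster 1 by -1.50 (adjusted p 8.27e-10), Tm4sf4 by -1.29, Cyp2j12 by -1.28, Dmkn by -1.16, Atp6v1b2 by -1.02, Nbl1 by -0.96, Gfra2 by -0.84 and Adra2a by -0.58. Slc6a2 (-0.38, adjusted p 0.000419), Th (-0.36, adjusted p 0.000422) and Dbh (-0.32, adjusted p 0.000240) were lower by less, and these 3 calls were lost without the set in the model, with adjusted p-values of 0.871, 0.924 and 0.381. The call for Ret (-0.25, adjusted p 0.0179) was lost with any 1 set left out, at adjusted p-values of 0.0942, 0.292 and 0.0508. Slc18a2, Vip, Chat, Slc18a3, Slc5a7, Sst, Prph, Ntrk3 and Atf3 did not pass. With median-of-ratios size factors Sst (2.54, adjusted p 6.76e-06) and Slc18a3 (-1.02, adjusted p 0.0256) passed, while Slc6a2 (adjusted p 0.0937) and Ret (adjusted p 0.128) did not. Sst also passed with the smaller pseudocount (0.71, adjusted p 0.0133), where Slc6a2 did not (adjusted p 0.200). The mean level of Sst was only 0.0724 in cluster 1 and 0.00516 in cluster 2, and that of Slc18a3 0.0159 and 0.0488. All lie below the 0.215 of Vip in cluster 1, which is not read as expression. The calls for Sst and Slc18a3 are therefore not read as differences in expression between clusters 1 and 2. Without the neurons richest in glial counts the difference of Th stayed at -0.36, with an adjusted p of 0.544. With cluster 3 in the model the differences of Th, Dbh and Slc6a2 were unchanged. Their adjusted p-values were then 0.295, 0.254 and 0.140, so they did not pass.

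In that comparison 24 of 68 OXPHOS subunits were lower in cluster 1 and 1 higher, or 34 and 1 when adjusted over the list alone (adjusted p 1.95e-12; adjusted p = 0.242 with an estimated correlation). Ribosomal protein genes had 15 of 79 higher and 0 lower, or 21 and 0 when adjusted over the list alone (1.11e-08; adjusted p = 0.336 with an estimated correlation). Hox genes had 2 of 6 higher, or 3 when adjusted over the list alone (0.000732; adjusted p = 0.242 with an estimated correlation). The cytoskeleton had 6 of 21 higher and 1 lower, or 8 and 4 when adjusted over the list alone (0.00535; adjusted p = 0.242 with an estimated correlation). Noradrenergic genes had 6 of 15 lower and 0 higher, or 8 and 2 when adjusted over the list alone (0.0389; adjusted p = 0.336 with an estimated correlation). Cholesterol biosynthesis had 4 of 23 higher, or 4 and 1 lower when adjusted over the list alone (0.0422; adjusted p = 0.318 with an estimated correlation), and interferon response genes 5 of 22 higher and 2 lower, or 6 and 3 when adjusted over the list alone (0.0422; adjusted p = 0.600 with an estimated correlation). The medians of these last lists turned below 0 without the neurons richest in glial counts. The other lists had no call, with adjusted p-values from 0.0564 for immediate early genes to 0.717 for sensory neuron markers. In total 936 of 10564 genes passed, 379 higher and 557 lower in cluster 1. Without the set in the model 282 genes passed, and between 422 and 550 passed with 1 set left out.

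Cluster 3 held 2 populations that differed in depth. Its 101 cells had either 1536 to 18608 counts, in 54 cells, or 52105 to 107665 counts, in 47 cells, with no cell between. The high-count cells had a median of 68061 counts and 8306 genes, against cluster medians of 28396 in cluster 1, 40121 in cluster 2 and 35488.5 in cluster 4. The low-count cells had a median of 2683.5 counts and 1531.5 genes. The populations were therefore described apart, a choice made after the data were seen.

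**Figure D3:**
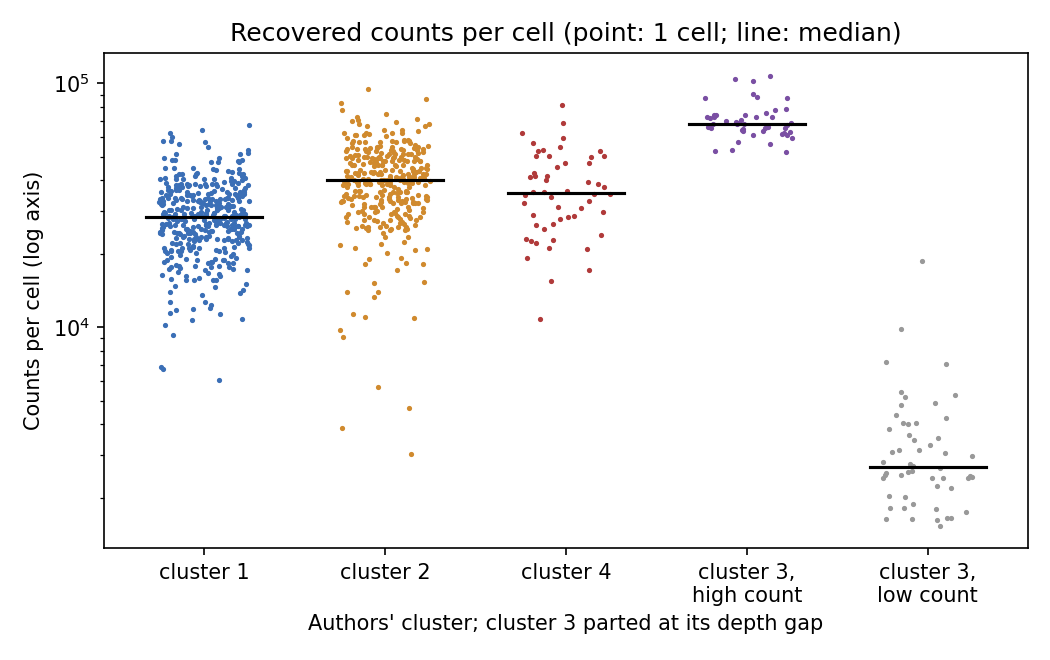
Counts per cell on a log axis, with each point a cell and lines at the medians. Cluster 3 is shown as 2 columns, parted at its gap between 18608 and 52105 counts.

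The high-count cells carried noradrenergic transcripts at levels that differed by gene, with little Npy. Slc6a2 averaged 20.1 ± 5.30 counts per 10000 (SD, n = 3 sets) and Th 47.6 ± 14.6, close to clusters 1 and 2, while Slc18a2 averaged 2.74 ± 0.321 against 4.62 ± 0.623 and 4.65 ± 0.952, and Npy 2.25 ± 1.28. Of 15 noradrenergic genes 6 were higher and 5 lower, or 6 and 6 when adjusted over the list alone, and the list had no call (adjusted p 0.819). Fxyd2 averaged 27.9 ± 3.35 and Thy1, a neuronal surface glycoprotein, 10.4 ± 1.08, against 3.56 ± 0.527, 7.21 ± 0.406 and 4.47 ± 0.513 in clusters 1, 2 and 4. Vip, at 0.143 ± 0.0393, and Slc18a3, at 0.0122 ± 0.00317, stood at the low levels of clusters 1 and 2. Ret averaged 2.69 ± 0.580, close to the 2.87 ± 0.471 of cluster 4.

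Against the mean of clusters 1, 2 and 4, limma gave log2 differences of 1.42 (SE 0.0451, adjusted p 1.93e-14) for Fxyd2, 1.14 for Thy1, 1.07 for Ddah1, 1.06 for Eef1e1, 0.95 for Nbl1, 0.91 for Slc6a2, 0.83 for Actr3b and 0.57 for Ret. Vip (-1.79), Cpne8 (-1.08), Cd81 (-0.97), Epha5 (-0.94), Nsg2 (-0.82), Elmo1 (-0.68) and Npy (-2.80, adjusted p 0.000847) were lower. Gal, at 24.0 ± 11.3, did not pass (0.56, adjusted p 0.256). Atf3 passed at 0.29 (adjusted p 0.0151) and lost its call without Set 3, at 0.0611. Cholinergic genes had 7 of 10 lower and 1 higher, or 8 and 1 when adjusted over the list alone (adjusted p 1.26e-08), and cholinergic neuron markers 6 of 8 lower and 1 higher, or 7 and 1 (1.26e-08). Neuropeptides had 7 of 12 lower and 1 higher, or 7 and 2 when adjusted over the list alone (3.06e-05), and dense-core granule proteins 7 of 17 lower and 1 higher, or 7 and 3 (6.37e-05). Hox genes had 4 of 6 lower and 0 higher, also when adjusted over the list alone (3.08e-05). Each of these 5 lists had an adjusted p of 0.0192 with an estimated correlation. Chga averaged 0.719 ± 0.0542 against 4.31 ± 0.548, 1.04 ± 0.0838 and 1.62 ± 0.105. Cholesterol biosynthesis genes had 13 of 23 higher and 0 lower, or 15 and 0 when adjusted over the list alone (6.37e-05; adjusted p = 0.0587 with an estimated correlation), with Mvk at 2.47 ± 0.669. Axon injury genes had 6 of 15 higher and 1 lower, or 7 and 3 when adjusted over the list alone (0.0127; adjusted p = 0.443 with an estimated correlation), with Gap43 at 32.6 ± 0.332. Immediate early genes had 8 of 18 lower and 2 higher, or 10 and 2 when adjusted over the list alone (7.24e-06; adjusted p = 0.0661 with an estimated correlation), and interferon response genes 7 of 22 lower and 2 higher, or 8 and 2 (7.24e-06; adjusted p = 0.245 with an estimated correlation). Chromaffin markers had 3 of 4 lower and 1 higher (0.00593; adjusted p = 0.0661 with an estimated correlation) and glial markers 2 of 8 lower and 1 higher (0.0141; adjusted p = 0.383 with an estimated correlation), the same counts when adjusted over the list alone. The other lists had no call, with adjusted p-values from 0.0667 for OXPHOS subunits to 0.970 for potassium channels. In total 2014 of 10518 genes passed, 1403 higher and 611 lower, and 601 passed without the set in the model. After each cell was thinned to 15000 counts, 961 genes passed, 514 higher and 447 lower, of which 784 were among the 2014. The excess of higher genes was also absent on summed counts with median-of-ratios size factors, with 699 higher and 686 lower. It was small on summed counts scaled only to the total, with 774 higher and 658 lower. The size factors alone therefore do not account for its loss. The cause of the excess was not tested. With those size factors Th lost its call (adjusted p 0.144) and Slc18a2 gained one (0.41, adjusted p 0.00113).

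Endothelial as well as neuronal transcripts were counted in the low-count cells, which were not tested as a neuron class. Their median level of sympathetic markers was 76.6 counts per 10000, against 24.4 for endothelial markers, and Npy averaged 30.5 ± 15.3, Th 18.4 ± 9.11 and Slc6a2 11.7 ± 9.88 (SD, n = 3 sets). Counts of the 11 endothelial markers averaged 85.6 per 10000 in the low-count cells of Set 1, 21.1 in Set 2 and 50.4 in Set 3, against 1.22, 1.25 and 1.65 in the other cells. Levels per 10000 rise in a cell with few counts even where the stray counts are the same, so counts per cell were compared too. They averaged 25.6, 7.26 and 22.6 in the low-count cells of Sets 1, 2 and 3 and 4.19, 5.01 and 5.86 in the other cells. Medians in the low-count cells were 26, 1 and 22, and Set 2, with the median of 1, held 31 of the 54 cells. Of the 54 cells, 21 held more counts of these markers than the 99th percentile of neurons, which is 38.9% (95% Clopper-Pearson interval 25.9 to 53.1). The same held for 10 cells with fibroblast markers and 7 with mural and smooth muscle markers. Pooled over the low-count cells, Npy and Vip stood at 31.0 and 1.34 per 10000 in Set 1, 41.4 and 3.75 in Set 2, and 34.5 and 1.39 in Set 3. In the other cells they stood at 91.3 and 2.72, 70.3 and 4.75, and 72.5 and 4.25. Whether RNA from other wells gave the neuronal counts was tested only for the cells above no marker list, and stays open for the rest.

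The sets differed from each other, which is described only as the size of the batch because a set differs in mice and in processing. Mitochondrial transcripts were highest in Set 2, where mt-Nd1 averaged 52.9 ± 1.19 counts per 10000 (SD over plates) against 34.7 ± 2.67 in Set 1 and 22.4 ± 2.27 in Set 3. Pkm, a glycolytic enzyme, and Syngr3, a synaptic vesicle protein, were highest in Set 3, at 23.9 ± 0.568 and 9.88 ± 0.355. Ppia averaged 7.29 ± 0.347 in Set 1, 1.04 ± 0.334 in Set 2 and 1.33 ± 0.173 in Set 3. With plates as technical replicates, limma called 1713 of 10464 genes between Sets 1 and 2, 2494 between Sets 1 and 3 and 3618 between Sets 2 and 3.

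Positions are on GRCm38, matched by symbol to an annotation of that build. Vip lies on chromosome 10 from 5639218 to 5647617, Npy on chromosome 6 from 49822710 to 49829507, Gal on chromosome 19 from 3409915 to 3414544 and Fst on chromosome 13 from 114452290 to 114458951. Slc6a2 lies on chromosome 8 from 92960079 to 93001667, Dbh on chromosome 2 from 27165233 to 27183200, Th on chromosome 7 from 142892752 to 142931128 and Fxyd2 on chromosome 9 from 45399669 to 45410278. Slc18a3, on chromosome 14 from 32462438 to 32464850, lies inside Chat, from 32408203 to 32465989 on the same strand, so reads in the shared part cannot be assigned to either gene with certainty.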

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

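The difference between clusters 1 and 2 itself differed between sets for 48 of 10421 genes, with 1038 at an unadjusted p under 0.05. Gnas had log2 differences of -1.21, -1.40 and -0.82 in Sets 1, 2 and 3 (limma, adjusted p 6.59e-05), so its direction held and its size varied. Slc18a2 had -0.14, -0.16 and 0.23 (adjusted p 0.00119), so its direction turned in Set 3. Plates served as technical replicates here, and no biological explanation was tested.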

How the results depend on the processing

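Without the set as a block, 586, 458 and 1118 genes passed for clusters 1, 2 and 4, 282 for cluster 1 against 2, 601 for the high-count cells and 2522 for the whole of cluster 3. Leaving out 1 set gave 877 to 998 for cluster 1, 664 to 814 for cluster 2, 422 to 550 for cluster 1 against 2, 1074 to 1326 for the high-count cells and 2397 to 3585 for the whole of cluster 3.

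Summed counts with voom weights gave 2478 genes for cluster 1, 2246 for cluster 2 and 2466 for cluster 1 against 2. Thinning gave 866, 741 and 491, with 961 for the high-count cells and 929 for cluster 3, of which thinning left 48 cells, nearly all high-count. The filter of 0.5 gave 973, 854 and 1328 for clusters 1, 2 and 4. Weights by cell number gave 2323, 2043 and 1605, and 2847 for cluster 1 against 2. The whole of cluster 3 gave 1307 with median-of-ratios size factors and 1366 with summed counts scaled to the total.

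With cluster 3 in the model, as the plan had it, 1004, 1046 and 1900 genes passed for clusters 1, 2 and 4, of which 65.6%, 75.1% and 69.0% were higher. Prph turned to 0.20 in cluster 1 and 0.16 in cluster 2. The mean set against each cluster then held cluster 3 with its low-count cells, so these are not the same differences. For cluster 1 against 2, whose difference stays the same, 414 genes passed. With median-of-ratios size factors the share of higher genes moved from 40.8% to 51.3% in cluster 1 and from 56.3% to 49.4% in cluster 2. It moved from 50.0% to 45.1% in cluster 4 and from 40.5% to 51.8% in cluster 1 against 2. In the high-count cells it moved from 69.7% to 50.5%, and in the whole of cluster 3 from 17.1% to 52.5%. These size factors were applied to summed counts. Summed counts scaled only to the total gave 46.7%, 53.2% and 45.8% for clusters 1, 2 and 4. They gave 44.2% for cluster 1 against 2, 54.1% for the high-count cells and 59.3% for the whole of cluster 3.

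With 1 set left out, the plate-level r ran from -0.123 to 0.323 for cluster 1, -0.403 to 0.561 for cluster 2, -0.753 to 0.773 for cluster 3 and -0.753 to -0.153 for cluster 4. Its direction turned with some set left out for clusters 1, 2 and 3, and for cluster 3 this was without Set 1. The cause was not tested. The comparisons of traced cells, and every setting planned for them, were not run, and only the plate-level substitute was. Apart from cluster 3 in the model, and median-of-ratios size factors, no block and leaving out each set for clusters 1, 2 and 4 and the whole of cluster 3, every setting given here was chosen after the data were seen.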

Other observations

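Cluster 4 held cells with and without Sst, a split defined here after the data were seen, with 3, 10 and 5 positive and 9, 12 and 13 negative cells in the 3 sets. The 2 cells with the most Atf3 were left out. A cell with any Sst count was positive, so the split also depends on depth and on stray counts. The fit left 2 residual degrees of freedom and took its spread from all genes together, so its p-values rest on that pooling. Th was lower in the Sst-positive cells, at 6.30 ± 1.51 counts per 10000 against 33.4 ± 11.0 (SD, n = 3 sets; log2 difference -2.45, limma adjusted p 0.000258). Dbh was higher in them, at 9.84 ± 1.53 against 5.41 ± 0.223 (0.84), and so was Slc18a2, at 0.849 ± 0.135 against 0.260 ± 0.0668 (0.48, adjusted p 0.0120), while Slc6a2 did not pass (0.08, adjusted p 0.902). Crip1 averaged 39.5 ± 2.18 against 15.8 ± 3.39, and Gda 3.41 ± 0.25 against 0.161. Vip, at 31.5 ± 17.1 against 65.7 ± 5.84, did not pass (adjusted p 0.206). The comparison called 459 of 10415 genes, against at most 0 in any other split, and the 10 splits are too few for a share under 0.05. No biological explanation was tested.

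The tests for the high-count cells of cluster 3 were all chosen after the result was seen. Pairs of neurons of clusters 1, 2 and 4 in 1 well could give high counts, and 1 gene, Agrp, was positive in more cells than random pairs allow, at 63.8% against at most 5.88% in a cluster, where pairs drawn within sets gave 0 such genes and clusters 1, 2 and 4 gave 7, 2 and 38. Fxyd2, at 27.9 ± 3.35 counts per 10000 against at most 21.1 ± 2.52, and Thy1, at 10.4 ± 1.08 against at most 7.21 ± 0.406, also lie above the range of the 3 clusters. Agrp is 1 gene found among all, and Fxyd2 and Thy1 are among the smallest p-values of this same comparison. These genes therefore do not decide the question. Npy and Vip were fixed in advance. At the levels given above, Npy in the high-count cells lay far below clusters 1 and 2, and Vip far below cluster 4. Random pairs would carry the Npy of clusters 1 and 2 or the Vip of cluster 4. The levels of Npy and Vip thus argue against random pairs, while pairs of a selected part of the cells stay open. Higher depth as the whole cause is argued against by 784 of the 2014 genes still called in the same direction after thinning to equal depth. Their median size was 0.27 against 0.24 before, but they were selected by passing after thinning, so this size adds no evidence. The other 1230 lost their call, with a median from 0.15 (quartiles 0.11 and 0.18) to 0.11 (0.06 and 0.16), and whether depth or fewer counts ended these calls was not tested. What these cells are stays open, and no biological explanation was tested.

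The tests for the low-count cells of cluster 3 were also chosen after the result was seen. RNA from other wells as the source of all their endothelial counts is argued against by 21 of the 54 cells with more such counts than the 99th percentile of neurons. These were 11 of 15 cells in Set 1, 5 of 31 in Set 2 and 5 of 8 in Set 3. Endothelial cells sorted into wells may account for these 21 cells, while for the other 33 RNA from other wells stays open. In the 13 cells above no marker list per 10000, Vip made up 5.46% of Npy plus Vip counts, against 4.72% in all other cells, 0.112% in cluster 1 and 94.7% in cluster 4, as RNA from other wells of the plate would give. The identity of those 13 cells stays open.

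The tests for lower OXPHOS transcripts in cluster 1 were chosen after the result was seen. The median log2 difference of the list was -0.19 after thinning, -0.21 with median-of-ratios size factors and -0.21 without the neurons richest in glial counts. These values argue against depth, scaling and glial RNA as causes. With cluster 3 in the model, and so in the mean set against cluster 1, the median was -0.03. The call of the list was lost with an estimated correlation. No biological explanation was tested.

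The splits were also chosen after the results were seen. For cluster 1 the real split called 1500 genes and the highest other 429, for cluster 4 2608 and 1563, for the high-count cells 2014 and 204 and for the whole of cluster 3 4313 and 524. For cluster 2, 1 other split called more, 1539 against 1301, so 2 of 100 splits reached the real count. The group set apart in that split held 0 of the 3 cluster 2 means, while the highest other split for cluster 4 kept all 3 cluster 4 means together. The clusters are groups of these same cells by their expression, so the real grouping is favoured in advance, and these splits do not show whether chance is excluded. For clusters 1 and 2 alone, 2320 genes were called against at most 0, and 10 splits are too few for a share under 0.05. The fit of clusters 1, 2 and 4 together called 936 genes between clusters 1 and 2, and why these counts differ was not tested. Differences between the sets gave 4343 genes against at most 927 in other splits of the plates, but plates of a set share 1 pool, so this does not exclude chance differences between pools.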
